A study of Mus musculus with 11 samples.

How the data were processed

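The data came from alphaTC1-6 cells, an immortalised mouse pancreatic alpha cell line that makes glucagon. Messenger RNA was sequenced from 11 libraries. Cells were transfected while being plated and collected 72 h later, at a stated confluency of 70% for transfection. There were 3 libraries with a scramble control, 4 with knockdown of Mettl3 and 4 with knockdown of Mettl14. RNA was isolated with Trizol and columns and made into stranded libraries, per the labels' protocols. The kind of knockdown reagent, the read length, the genome build and the annotation are not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

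The authors deposited one table of estimated counts per gene, with one column per library, keyed by Ensembl gene identifiers. Kallisto, which assigns reads to transcripts without a full alignment, is named in the submitters' processing notes, with no version. How transcript estimates were added up to genes is not given in the sources used here. The deposited expected counts were not scaled to a common total, since the totals differed between columns, and 11.6% of the values were not whole. Whether the counts were scaled by transcript length is not given in the sources used here. They were rounded to whole numbers before testing. No column of another sample was present in the table. Because reads that match several transcripts are shared out by estimation, genes with near-identical copies, such as ribosomal protein genes with processed pseudogenes and the Hba pair, carry more uncertainty than their counts show.

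The table had 53947 gene rows, of which 48651 matched a symbol in the mouse gene name tables used here. Rows without a symbol held 0.518% of all counts. The authors' build is not given in the sources used here, so the reference served for symbols and transcript properties alone, and no coordinates are reported. Of the 14133 genes tested, 13731 had a symbol and 402 did not.

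Library totals ran from 19576632 counts in scramble replicate 2 to 22406527, with 20944085 in Mettl14 KD replicate 2 and at least 22238687 in the other 9. CPM values, computed from the rounded counts, were scaled by the trimmed mean of M-values, TMM. The filterByExpr function of edgeR, with a minimum count of 10, kept genes holding 99.9% of all counts. The common biological coefficient of variation was 4.38%, with 8 residual degrees of freedom. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of libraries of one group differed by so little that it could be sampling noise: chi-square per degree of freedom was 2.11 or more for each replicate pair.

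The comparisons were fixed before the data were examined: each knockdown against scramble, and one knockdown against the other. All 11 libraries entered one fit with a mean per group. The test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with robust dispersion estimates and Benjamini-Hochberg adjustment at 0.05. Each SE was taken as the absolute log2 fold change divided by the square root of F, which is an approximation. Values after ± are SD over libraries for CPM and SE for log2 fold changes, with n = 3 for scramble and n = 4 for each knockdown.

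The named genes followed a rule fixed beforehand. Mettl3, Mettl14 and Gcg were always named. Next came the 6 genes with the largest change in each direction that passed the test, had a mean of at least 50 normalised counts and showed no overlap between the groups. From each fixed list with a call, the 2 members with the smallest adjusted p were named for each knockdown against scramble; the values of some of these members are not reported here. Other genes are said to have been chosen after their values were seen.

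In all, 25 gene lists with 535 gene names were fixed before the data were examined. Each was counted over all genes tested and again adjusted over the list alone. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, then with an estimated correlation, and with fry, adjusted over the lists of each comparison.

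Recovery was tested on simulated data in which 67 genes changed 1.2-fold, 67 changed 1.5-fold and 66 changed 2-fold. For Mettl3 KD against scramble, over 13982 genes, 53.7% of changes of 1.2-fold, 74.6% of 1.5-fold and 81.8% of 2-fold were recovered. For Mettl14 KD against scramble, over 13972 genes, these shares were 52.2%, 76.1% and 86.4%. For Mettl3 KD against Mettl14 KD, over 13987 genes, they were 52.2%, 77.6% and 87.9%. Unchanged genes gave 9, 9 and 7 calls. Far fewer genes changed there than the 4420, 2956 and 1145 called in the data. The Benjamini-Hochberg cutoff on p is stricter when fewer genes change, so these shares may understate recovery in the data. Because both knockdowns share the scramble libraries, unchanged groups were simulated 20 times against shared controls.

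Alternatives were DESeq2 1.42.0, its size factors in edgeR, library size alone, no low-count filter, at least 1 CPM in 3 samples, limma-voom with and without quality weights, fits of only the compared groups, a test against a fold of 1.2, the replicate number as a block, and each library left out. Leaving out both shallow libraries and removing a loess trend on transcript length were chosen after the data were seen.

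For checks of length, GC content and sequence motifs, one transcript per gene was taken from the GENCODE M21 mouse transcripts: principal isoforms first, then the longest coding sequence, then the longest transcript. A length was found for 97.2% of tested genes. Motifs of the m6A consensus DRACH were counted as far from an exon junction when more than 100 bases from one. Random lists, 10000 per comparison, were matched on length and GC content in 10 bins each. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.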

Results

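RNA from 11 libraries of alphaTC1-6 cells was compared: 3 scramble controls, 4 with Mettl3 knocked down and 4 with Mettl14 knocked down, all collected 72 h after knockdown. Mettl3 and Mettl14 form the core of the nuclear complex that writes N6-methyladenosine, m6A, on messenger RNA; Mettl3 carries the catalytic site and Mettl14 helps bind RNA. The design sets either subunit's knockdown against the same control and allows the knockdowns to be compared with each other. Library totals ran from 19576632 to 22406527 counts.

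The targeted transcripts were lower in the libraries labelled with their knockdown. Mettl3 was at 14.9 ± 1.02 CPM in scramble, 5.34 ± 0.449 CPM in Mettl3 KD and 15.4 ± 1.02 CPM in Mettl14 KD, so that Mettl3 KD libraries held 35.8% of the scramble level. Mettl14 was at 25.2 ± 1.70 CPM in scramble and 14.7 ± 0.720 CPM in Mettl14 KD, 58.1% of scramble, and it rose to 29.3 ± 1.02 CPM in Mettl3 KD. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with each knockdown library below each scramble library for its own target, the log2 fold changes were -1.48 ± 0.08 for Mettl3 in Mettl3 KD (adjusted p = 6.86e-11), -0.78 ± 0.06 for Mettl14 in Mettl14 KD (adjusted p = 8.78e-09) and 0.22 ± 0.06 for Mettl14 in Mettl3 KD (adjusted p = 0.00494). Mettl3 in Mettl14 KD did not pass the test, at 0.05 ± 0.07 (adjusted p = 0.692 by edgeR's quasi-likelihood test).

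**Figure D1:**
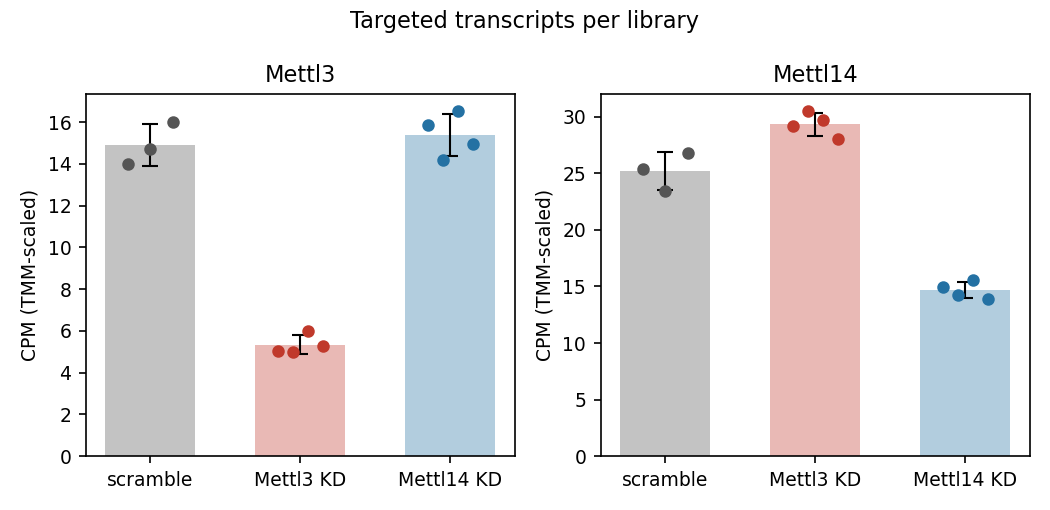
Mettl3 (left) and Mettl14 (right) in CPM for each library of the 3 groups; points are libraries, bars are group means and error bars are SD. Each targeted transcript was lowest in its own knockdown, at 5.34 CPM for Mettl3 and 14.7 CPM for Mettl14.

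Scramble replicate 2 stood apart from the other libraries. It had 19576632 counts, against 22238687 and 22397894 in the other scramble libraries, and lay at -38.1 on principal component 1, against -10.2 and -12.6. It also held transcripts typical of lung and blood: Sftpc, which encodes a lung surfactant protein, had 36.1 CPM, against a median of 0.762 CPM in the other libraries, and Scgb1a1, a secretory protein of airway club cells, had 34.2 against 0.830 CPM, both without TMM scaling. A list of 24 such transcripts, written after this library was seen, summed to 175 CPM there and to at most 10.7 CPM elsewhere. Genes with transcripts under 1000 bases had a median of -0.13 on the log2 scale against the other scramble libraries. Values without this library stand beside many of the gene groups below.

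**Figure D2:**
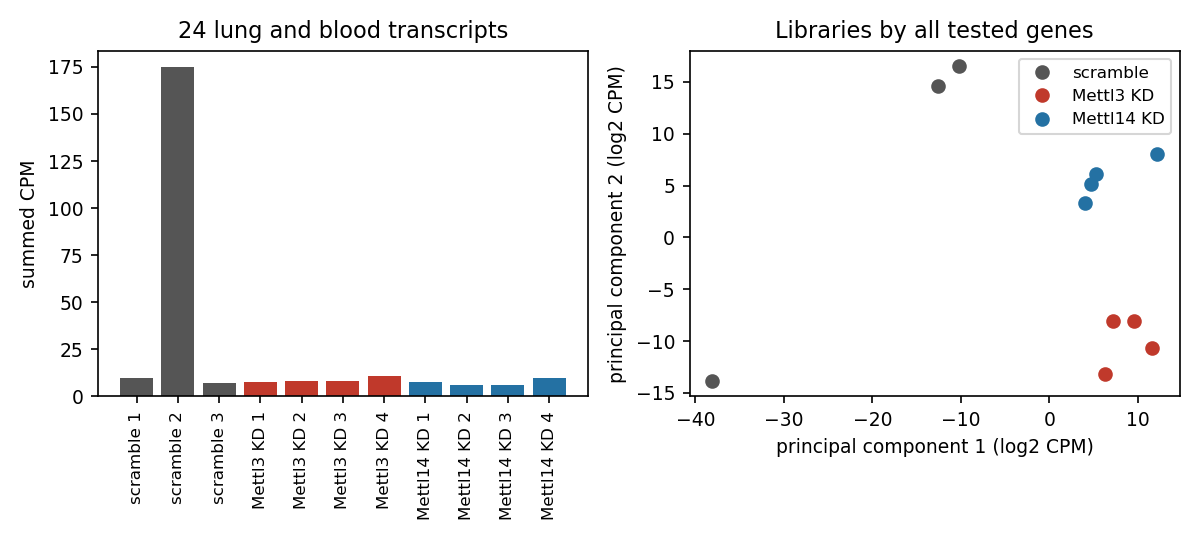
Left, summed CPM of 24 lung and blood transcripts per library; right, the libraries on principal components 1 and 2 of log2 CPM over all tested genes, coloured by group. Scramble replicate 2 reached 175 CPM and lay at -38.1 on component 1.

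With Mettl3 knocked down, 22 of 24 genes of sterol synthesis and 18 of 20 of glycolysis fell, while 20 of 35 genes of oxidative phosphorylation and 26 of 39 ribosomal protein genes rose by smaller amounts. Camera called these lists with a preset correlation and none of them with an estimated one (adjusted p = 0.169, adjusted p = 0.302, adjusted p = 0.408 and adjusted p = 0.357). Fry, which tests whether a list moves one way, called all of them (adjusted p = 8.65e-07, adjusted p = 0.000101, adjusted p = 0.00354 and adjusted p = 0.00240). Unlike camera, fry does not set a list against the other genes, and 31.3% of all genes passed edgeR's test here. Among the largest decreases were those of Sprr1a, a cornified envelope protein, at 1.64 ± 0.425 against 8.76 ± 0.498 CPM, 5.33-fold lower, and Adm, the peptide hormone adrenomedullin, at 5.71 ± 0.596 against 19.8 ± 0.764 CPM, 3.48-fold lower. Of the genes named by size, the largest increase was that of Ccnd2, encoding cyclin D2, at 14.8 ± 1.10 against 7.33 ± 0.526 CPM, 2.02-fold higher. Gcg, encoding glucagon, was at 32823 ± 772 CPM against 33703 ± 4301 CPM in scramble and did not pass edgeR's quasi-likelihood test (log2 fold change -0.04 ± 0.07, adjusted p = 0.708). Its log2 fold change turned on scramble replicate 2, where Gcg was lowest among the scramble libraries at 28738 CPM: it was -0.14 ± 0.03 and passed without that library, and was 0.01 ± 0.07 and 0.03 ± 0.07 without scramble replicate 1 or 3.

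In sterol synthesis, 22 of 24 measured genes fell in Mettl3 KD and the others did not pass, with a median log2 fold change of -0.46; adjusted over the list alone the count was also 22. Fdps, farnesyl diphosphate synthase, fell by 0.67 ± 0.03 on the log2 scale. In glycolysis 18 of 20 fell and 1 rose, with a median of -0.60 (19 and 1 adjusted over the list alone). Ldha, lactate dehydrogenase A, fell by 1.35 ± 0.17, and the aldolases Aldoc and Aldoa fell by 1.29 ± 0.07 and 0.57 ± 0.04. Camera with a preset correlation called both lists lower, with adjusted p = 2.20e-19 for sterol synthesis and 6.07e-13 for glycolysis; with an estimated correlation, adjusted p = 0.169 and adjusted p = 0.302. Without scramble replicate 2, 24 sterol genes and 19 glycolysis genes were lower.

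Of 35 nuclear-encoded genes of oxidative phosphorylation, 20 rose and 1 fell in Mettl3 KD, with a median of 0.20 (27 and 1 adjusted over the list alone). Sdhb, an iron-sulphur subunit of complex II, rose by 0.30 ± 0.03 and Cox7a2, a subunit of complex IV, by 0.23 ± 0.04. Of 39 cytosolic ribosomal protein genes, 26 rose and the others did not pass, also with a median of 0.20 (29 adjusted over the list alone), among them Rpl13a at 0.24 ± 0.04. Camera gave adjusted p = 2.03e-08 and 1.25e-09 with a preset correlation; with an estimated correlation, adjusted p = 0.408 and adjusted p = 0.357. Many of these transcripts are short, and scramble replicate 2 had fewer counts on short transcripts; without it 24 and 25 members were higher, with medians of 0.12 and 0.14. Of 13 mitochondrially encoded transcripts 1 rose, mt-Nd4l at 0.42 ± 0.13 (0 adjusted over the list alone). Its call ended without scramble replicate 2, at 0.35 ± 0.14, and also without scramble replicate 3, any of the 4 Mettl3 KD replicates or Mettl14 KD replicate 4, at 0.39 to 0.44. With scramble replicate 2 left out, 2 other members were higher, and the list's median went from -0.03 to 0.09. Likewise 2 were higher without Mettl3 KD replicate 4, and 1 was lower without Mettl14 KD replicate 3. The 1 lower oxidative phosphorylation gene was not called without Mettl3 KD replicate 2 or 3.

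Among alpha cell genes in Mettl3 KD, 8 of 20 transcription factors fell and the others did not pass (9 adjusted over the list alone), with a median of -0.10. Meis2, a homeobox factor, fell by 0.50 ± 0.07 and Pou3f4, a POU domain factor of alpha cells, by 0.17 ± 0.04. The camera test gave adjusted p = 0.00193 with a preset correlation and adjusted p = 0.302 with an estimated correlation. Without Mettl3 KD replicate 2, 5 of these factors were lower. Of 16 genes for glucagon processing and granule proteins, 4 rose and 4 fell (5 and 5 adjusted over the list alone), with a median of 0.02. With scramble replicate 2 left out, 4 were higher and 6 lower, with a median of -0.02. Among them, Vgf, a granin-like precursor, fell by 0.88 ± 0.05 and Ptprn, a phosphatase-like granule membrane protein, by 0.23 ± 0.03. In exocytosis 7 of 22 fell and 3 rose (8 and 3 adjusted over the list alone), with Unc13a, a vesicle priming factor, at -0.36 ± 0.03 and Cplx1, complexin 1, at 0.27 ± 0.04. Camera did not call this list, with adjusted p = 0.0661 with a preset correlation and adjusted p = 0.408 with an estimated correlation, though it called it lower without Mettl3 KD replicate 1. With Mettl3 KD replicate 3 left out, 4 members were lower. Of 15 excitability channels 5 fell (5 adjusted over the list alone), including the KATP subunit Abcc8 at -0.27 ± 0.04, and 2 others were higher without scramble replicate 2. Of 12 alpha cell surface and other markers 4 rose and 3 fell (4 and 3 adjusted over the list alone), with Tm4sf4 at 0.46 ± 0.07 and Ttyh1 at -0.32 ± 0.03. Of these markers 1 was lower without scramble replicate 3.

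Stress and growth lists were counted in Mettl3 KD as well. For the ATF4 and amino acid response 12 of 24 fell and 1 rose (14 and 1 adjusted over the list alone); Trib3, a pseudokinase, fell by 0.81 ± 0.09 and Ppp1r15a, a phosphatase subunit acting on eIF2alpha, by 0.37 ± 0.04. Camera gave adjusted p = 0.000175 with a preset correlation and adjusted p = 0.260 with an estimated correlation. Of 18 p53 targets 9 rose and 4 fell (11 and 4 adjusted over the list alone). Ccng1, cyclin G1, rose by 0.62 ± 0.06 and the kinase Plk2 by 0.46 ± 0.04, while Cdkn1a, the cell cycle inhibitor p21, chosen after its value was seen, fell by 0.41 ± 0.06. For this list camera gave adjusted p = 0.0443 with a preset correlation and adjusted p = 0.260 with an estimated correlation. Of 19 immediate early genes 10 fell and 4 rose (10 and 4 adjusted over the list alone), with Ier3 at -0.81 ± 0.05 and Fosl2 at -0.40 ± 0.04. Of 14 serine/arginine splicing factors 5 rose and 1 fell (6 and 1 adjusted over the list alone), with Srsf7 at 0.25 ± 0.04 and Srsf6 at 0.14 ± 0.03. For these factors camera gave adjusted p = 0.0280 with a preset correlation and adjusted p = 0.469 with an estimated correlation. Without scramble replicate 2 camera called neither p53 targets nor splicing factors. The p53 call also ended without scramble replicate 3, Mettl3 KD replicate 2 or 3, or Mettl14 KD replicate 1, and the splicing factor call without Mettl3 KD replicate 2. Splicing factors had 8 higher without scramble replicate 1 and 3 higher without Mettl3 KD replicate 1, 2 or 3 or Mettl14 KD replicate 3. Their 1 lower member was not called without scramble replicate 2 or 3, Mettl3 KD replicate 1, 2 or 4, or Mettl14 KD replicate 1 or 4. Camera did not call immediate early genes, with adjusted p = 0.0521 with a preset correlation and adjusted p = 0.469 with an estimated correlation, though it called them lower without scramble replicate 1 or 3, Mettl3 KD replicate 1 or 4, or Mettl14 KD replicate 4.

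Other lists were mixed in Mettl3 KD. In the m6A writer complex 4 of 8 rose and 1 fell (4 and 2 adjusted over the list alone), including Virma at 0.20 ± 0.03, and of 13 erasers and readers 4 rose and 1 fell (4 and 1 adjusted over the list alone), with the demethylase Alkbh5 at -0.38 ± 0.04 and the methyltransferase Mettl16 at 0.31 ± 0.06. Mettl16 is counted in the list of erasers and readers, although it is neither. In the writer complex 2 were lower without scramble replicate 1 and 2 higher without Mettl3 KD replicate 2. Of erasers and readers 2 were higher without scramble replicate 3 or Mettl3 KD replicate 3. Insulin and IGF signalling had 6 of 22 higher and 3 lower (8 and 4 adjusted over the list alone), with Foxo3 at -0.38 ± 0.04 and Pik3r1 at 0.26 ± 0.04. ER chaperones and degradation genes had 6 of 22 higher and 3 lower (8 and 3 adjusted over the list alone), with Dnajb11 at 0.32 ± 0.04 and Dnajb9 at -0.43 ± 0.05. Replication genes had 1 of 25 higher and 4 lower (2 lower adjusted over the list alone), with Chaf1b and E2f1 at -0.14 ± 0.04 each, and mitotic genes 4 of 25 higher and 3 lower (4 and 3 adjusted over the list alone), with Birc5 at 0.16 ± 0.04 and Ccna2 at -0.13 ± 0.03. Mitotic genes had 4 higher and 5 lower without scramble replicate 2. Of replication genes 2 were lower without Mettl3 KD replicate 1, 2 or 3 or Mettl14 KD replicate 1 or 4, and 2 were higher without scramble replicate 3. The 1 higher replication gene was not called without scramble replicate 2, Mettl3 KD replicate 1, 3 or 4, or Mettl14 KD replicate 3. The median, the mean and the direction of camera's test differed in sign for the writer complex (median 0.09, mean -0.09, test higher) and for granule genes (median 0.02, mean -0.04, test lower), and, with values near 0, for erasers and readers, surface markers, delta, PP and epsilon markers, mitotic genes, ER genes and mitochondrially encoded transcripts.

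Markers of other cell types in Mettl3 KD included 1 of 8 beta cell markers higher and 3 lower (1 and 4 adjusted over the list alone), with Slc30a8, a granule zinc transporter, at 0.29 ± 0.03 and G6pc2, islet glucose-6-phosphatase, at -0.27 ± 0.04. Of 6 acinar and ductal markers 1 rose and 2 fell (1 and 2 adjusted over the list alone), with the keratin Krt7 at -1.15 ± 0.13, and of 3 delta, PP and epsilon markers 1 rose and 1 fell (1 and 1 adjusted over the list alone), with Sstr3 at -0.17 ± 0.05. The Sstr3 call ended without scramble replicate 3, at -0.15. Of acinar and ductal markers 1 was lower without scramble replicate 2 or 3, Mettl3 KD replicate 2, 3 or 4, or Mettl14 KD replicate 2 or 4. Of 22 interferon-stimulated genes 7 fell (7 adjusted over the list alone), with a median of -0.28 and H2-D1 at -0.24 ± 0.04 and Stat2 at -0.29 ± 0.06. The camera test gave adjusted p = 0.0190 with a preset correlation and adjusted p = 0.601 with an estimated correlation. Without scramble replicate 2, 3 fell, the median was -0.06 and camera made no call. Of 8 mesenchymal, endothelial and immune markers 0 passed edgeR's test (0 adjusted over the list alone), 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom, with and without quality weights, called 0; their median was -1.09 with all libraries and 0.84 without scramble replicate 2, when 3 were higher; 1 was lower without scramble replicate 1 or 3.

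Over all 14133 genes, edgeR's quasi-likelihood test called 2184 genes higher and 2236 lower in Mettl3 KD than in scramble. Most changes were small: 48 of the genes called higher and 372 of those called lower passed 1.5-fold. The groups did not overlap for 35.5% of genes, against 5.71% by chance. The other genes named by size were Inka2 (1.88-fold), Nme4 (1.83-fold), Zfhx2 (1.79-fold), Cldn1 (1.78-fold) and Lrrc4 (1.75-fold) among those higher, and C3 (4.21-fold) and Mgarp (2.61-fold) among those lower. C3, complement component 3, had 15.9 CPM in scramble replicate 2 and 3.49 and 3.54 CPM in the other scramble libraries; its log2 fold change was -2.07 ± 0.59 with that library and -0.98 ± 0.18 without it, and its call ended without Mettl3 KD replicate 1, 2 or 4, at -1.98 to -2.07. The test called 4343 genes without scramble replicate 2, against 4420 with it. Camera called 9 of 25 lists with a preset correlation and 0 with an estimated one, and fry called 12.

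**Figure D3:**
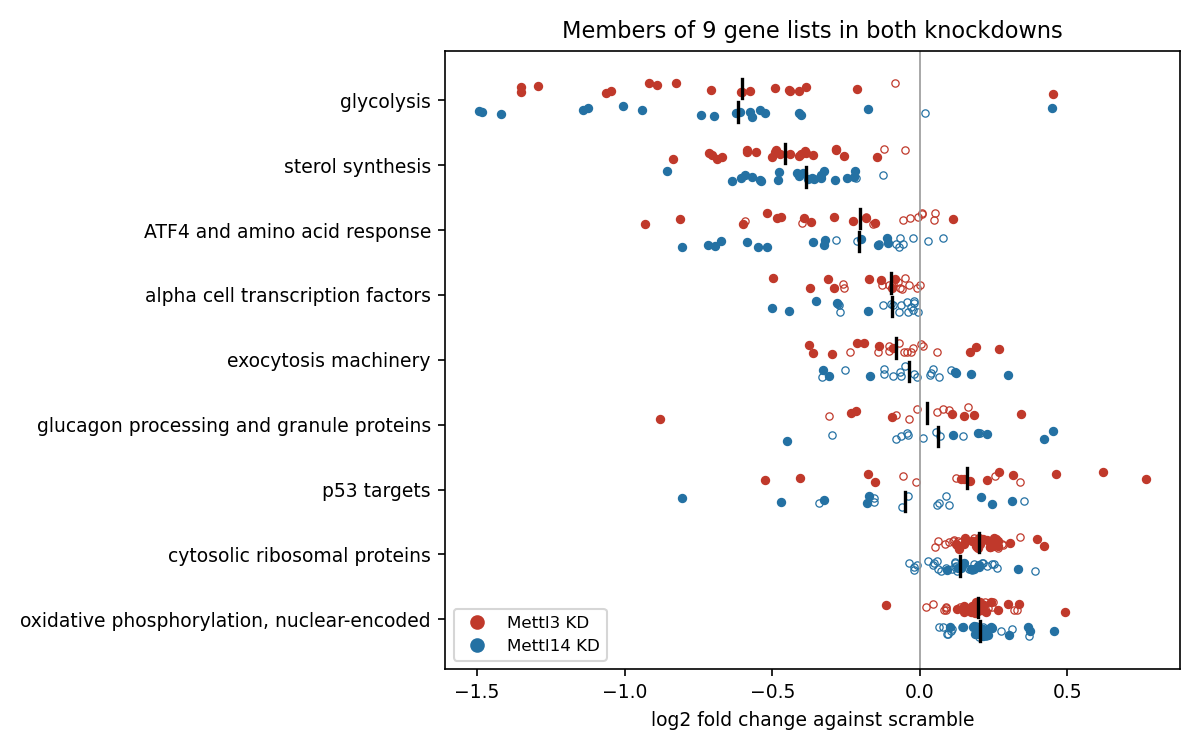
Log2 fold change against scramble for each measured member of 9 gene lists in Mettl3 KD (red) and Mettl14 KD (blue); filled points passed edgeR's test, open points did not, and black bars are list medians. Glycolysis had medians of -0.60 and -0.62, sterol synthesis -0.46 and -0.39.

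With Mettl14 knocked down, sterol synthesis and glycolysis genes again fell, 22 of 24 and 18 of 20, and 21 of 35 oxidative phosphorylation genes rose. Camera called these lists with a preset correlation and none of them with an estimated one (adjusted p = 0.0927, adjusted p = 0.246 and adjusted p = 0.246). Fry called all of them (adjusted p = 1.60e-06, adjusted p = 6.77e-05 and adjusted p = 0.00255). Sprr1a was at 1.73 ± 0.111 against 8.76 ± 0.498 CPM in scramble, 5.05-fold lower, and Adm at 5.61 ± 1.15 against 19.8 ± 0.764 CPM, 3.52-fold lower. Nr4a1, an orphan nuclear receptor induced by cell stimulation, had the largest increase of the genes named by size, to 78.9 ± 4.12 from 42.4 ± 4.19 CPM, 1.86-fold. Gcg was at 37289 ± 1003 CPM against 33703 ± 4301 CPM and did not pass edgeR's quasi-likelihood test (log2 fold change 0.15 ± 0.07, adjusted p = 0.150); without scramble replicate 2 it was 0.04 ± 0.03 and did not pass either.

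In Mettl14 KD, 22 of 24 sterol synthesis genes fell, with a median of -0.39 (23 adjusted over the list alone), Fdps by 0.59 ± 0.03. In glycolysis 18 of 20 fell and 1 rose, with a median of -0.62 (18 and 1 adjusted over the list alone), Aldoc by 1.42 ± 0.07 and Gpi1, glucose-6-phosphate isomerase, by 0.57 ± 0.04. Camera gave adjusted p = 3.95e-24 and 2.37e-16 with a preset correlation; with an estimated correlation, adjusted p = 0.0927 and adjusted p = 0.246. With scramble replicate 2 left out, 24 and 18 members were lower.

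Of the oxidative phosphorylation genes 21 of 35 rose in Mettl14 KD, with a median of 0.20 (28 adjusted over the list alone), including Sdhb at 0.30 ± 0.03 and Uqcrc1, a core subunit of complex III, at 0.24 ± 0.03. Of the ribosomal protein genes 10 of 39 rose, with a median of 0.14 (15 adjusted over the list alone), including Rps18 at 0.20 ± 0.04. Camera gave adjusted p = 6.56e-13 and 1.16e-06 with a preset correlation; with an estimated correlation, adjusted p = 0.246 and adjusted p = 0.476. Without scramble replicate 2, which had fewer counts on short transcripts, 27 and 10 were higher, with medians of 0.14 and 0.08. Leaving out scramble replicate 1 or 3 gave 16 higher ribosomal protein genes. Of 13 mitochondrially encoded transcripts 1 rose, mt-Nd4l at 0.57 ± 0.13 (1 adjusted over the list alone), a call that ended without scramble replicate 2, at 0.50 ± 0.14. Another member was higher without that library, and the list's median went from 0.02 to 0.08.

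For alpha cell genes in Mettl14 KD, 5 of 20 transcription factors fell (6 adjusted over the list alone), with Meis2 at -0.50 ± 0.07 and Foxp4, a forkhead factor, at -0.35 ± 0.06. For the factors camera gave adjusted p = 0.000726 with a preset correlation and adjusted p = 0.246 with an estimated correlation. Of 16 granule genes 5 rose and 1 fell (5 and 1 adjusted over the list alone): Ttr, transthyretin, rose by 0.45 ± 0.05 and Vgf fell by 0.45 ± 0.05; 2 were lower without scramble replicate 2. In exocytosis 4 of 22 rose and 3 fell (4 and 3 adjusted over the list alone), with Cplx1 at 0.30 ± 0.04 and Unc13a at -0.33 ± 0.03. Of the 22, 5 were lower without scramble replicate 2 and 6 without scramble replicate 1. Of 15 channels 4 fell (4 adjusted over the list alone), with Abcc8 at -0.16 ± 0.04. The channels' median went from 0.01 to 0.08 without scramble replicate 2, with 1 higher and 3 lower, and 1 was higher without Mettl14 KD replicate 1. Leaving out scramble replicate 3 gave 2 lower channels. Of 12 surface and other markers 3 rose and 2 fell (4 and 2 adjusted over the list alone), with Tm4sf4 at 0.44 ± 0.07 and Ttyh1 at -0.22 ± 0.03.

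Of the ATF4 and amino acid response genes 14 of 24 fell in Mettl14 KD (16 lower and 1 higher adjusted over the list alone), including Vldlr, a lipoprotein receptor, at -0.59 ± 0.05 and Ppp1r15a at -0.36 ± 0.04. For this list camera gave adjusted p = 1.86e-07 with a preset correlation and adjusted p = 0.102 with an estimated correlation. Of 18 p53 targets 3 rose and 5 fell (4 and 5 adjusted over the list alone), with Plk2 at 0.31 ± 0.04 and the apoptosis gene Bbc3 at -0.80 ± 0.12. Of 19 immediate early genes 5 rose and 8 fell (5 and 11 adjusted over the list alone), Nr4a1 by 0.90 ± 0.07 upward and Ier3 at -0.85 ± 0.05. Of 14 splicing factors 4 rose (5 adjusted over the list alone), with Srsf7 at 0.22 ± 0.04 and Tra2a at 0.18 ± 0.04. Here camera gave adjusted p = 0.00157 with a preset correlation and adjusted p = 0.387 with an estimated correlation. Of these factors 7 were higher without scramble replicate 1.

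Smaller counts came from the remaining lists in Mettl14 KD. In the writer complex 2 of 8 fell (2 lower and 1 higher adjusted over the list alone), Mettl14 itself and Rbm15 at -0.19 ± 0.04. In the list of 13 erasers and readers Alkbh5 fell by 0.42 ± 0.04 and the methyltransferase Mettl16 rose by 0.21 ± 0.06 (1 and 1 adjusted over the list alone). The Mettl16 call ended without scramble replicate 2, at 0.13 ± 0.05. In the writer complex 1 was higher without scramble replicate 1 or 3. Insulin and IGF signalling had 3 of 22 higher and 2 lower (3 and 2 adjusted over the list alone), with Foxo3 at -0.46 ± 0.04 and Pik3r1 at 0.28 ± 0.04; 1 was lower without scramble replicate 2 or Mettl14 KD replicate 2. ER genes had 2 of 22 higher and 2 lower (2 and 4 adjusted over the list alone), with Dnajb11 at 0.24 ± 0.04 and Calr at 0.18 ± 0.04. Of the ER genes, 5 were lower without scramble replicate 2, and 4 without scramble replicate 1, Mettl3 KD replicate 3 or Mettl14 KD replicate 3. Replication genes had 4 of 25 lower (4 adjusted over the list alone), with Chaf1b at -0.20 ± 0.04 and E2f1 at -0.18 ± 0.04. Camera did not call replication genes, with adjusted p = 0.556 with a preset correlation and adjusted p = 0.835 with an estimated correlation, though it called them lower without scramble replicate 2. Of replication genes 2 were higher without scramble replicate 3, and 2 were lower without Mettl14 KD replicate 1 or 2. Mitotic genes had 3 of 25 higher and 2 lower (3 and 2 adjusted over the list alone), with Aurkb at -0.21 ± 0.05 and Ccnb1 at 0.13 ± 0.03; 1 was lower without scramble replicate 2 or 3 or Mettl14 KD replicate 1, 2 or 4. The median, the mean and camera's direction differed in sign for the writer complex (median 0.01, mean -0.09, test lower), ER genes (median 0.01, mean -0.06, test higher), surface markers, erasers and readers, and channels.

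Among markers of other cells in Mettl14 KD, 4 of 8 beta cell markers fell and 1 rose (5 and 1 adjusted over the list alone), with G6pc2 at -0.31 ± 0.04 and Slc30a8 at 0.19 ± 0.03. For beta cell markers camera gave adjusted p = 0.0120 with a preset correlation and adjusted p = 0.246 with an estimated correlation. Of 6 acinar and ductal markers 1 fell, Krt7 at -0.80 ± 0.13 (1 adjusted over the list alone), and of 3 delta, PP and epsilon markers 0 passed edgeR's test (0 adjusted over the list alone), 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom, with and without quality weights, called 0; without scramble replicate 2, 1 was higher. Of 22 interferon-stimulated genes 4 fell (3 adjusted over the list alone), with H2-K1 at -0.56 ± 0.11 and H2-D1 at -0.14 ± 0.04. Camera gave adjusted p = 0.0362 with a preset correlation and adjusted p = 0.682 with an estimated correlation, and without scramble replicate 2 it made no call, with 2 lower, 1 higher and a median of -0.07 in place of -0.15. That call also ended without Mettl14 KD replicate 1 or 2. Of 8 mesenchymal, endothelial and immune markers 1 fell, Cd68 at -0.80 ± 0.21 (1 adjusted over the list alone); their median was -1.58 with all libraries and 0.19 without scramble replicate 2. Camera did not call these markers, with adjusted p = 0.0902 with a preset correlation and adjusted p = 0.682 with an estimated correlation, though it called them lower without scramble replicate 1 or 3, when 2 and 3 members were lower.

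Over all genes, edgeR's quasi-likelihood test called 1424 genes higher and 1532 lower in Mettl14 KD than in scramble, and 32 and 224 of these passed 1.5-fold. The groups did not overlap for 28.9% of genes, against 5.71% by chance. Other genes named by size were Kcnh1 (1.79-fold), Zfhx2 (1.75-fold), Ccnd2 (1.74-fold), Lrrc4 (1.73-fold) and Gucy2c (1.70-fold) among those higher, and C3 (4.94-fold), Selenbp1 (3.33-fold), Mgarp (3.15-fold) and Colgalt2 (2.88-fold) among those lower. For C3, raised in scramble replicate 2, the log2 fold change was -2.30 ± 0.61 with that library and -1.20 ± 0.19 without it, and its call ended without any 1 of the 4 Mettl14 KD libraries, at -2.20 to -2.41. There were 2786 calls without scramble replicate 2, against 2956 with it. Camera called 9 of 25 lists with a preset correlation and 0 with an estimated one, and fry called 10.

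Genes called in both knockdowns moved in one direction in nearly all cases: 1050 were higher in both, 1201 lower in both and 16 went opposite ways. Sprr1a, Adm, Mgarp, C3, Ccnd2, Zfhx2 and Lrrc4 were named by size in each; without scramble replicate 2 the log2 fold changes of C3 went from -2.07 to -0.98 in Mettl3 KD and from -2.30 to -1.20 in Mettl14 KD. Independent lists of these sizes would share 462 genes in the same direction. Unchanged groups simulated against the shared scramble libraries shared 0.1 on average, with 0.45 calls on average in Mettl3 KD and 0.55 in Mettl14 KD. With so few calls they could share almost none, so that value does not bear on the observed overlap. The simulation drew each gene's noise independently, so it held no difference running through many genes, such as that of scramble replicate 2. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.736 and Spearman's rho 0.749; simulated unchanged groups gave r of 0.593 on average, from 0.486 to 0.665. The covariance was 0.0670 against 0.0221 simulated, a difference of 0.0449. It was 0.131 without scramble replicate 1 and 0.106 without scramble replicate 3, for which no unchanged groups were simulated, 0.550 with DESeq2 and 0.696 without a low-count filter, so the size of that difference depends on the setting. Scramble, with 3 libraries, could not be divided into parts of 2 libraries each, so part of the excess may come from the shared controls.

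**Figure D4:**
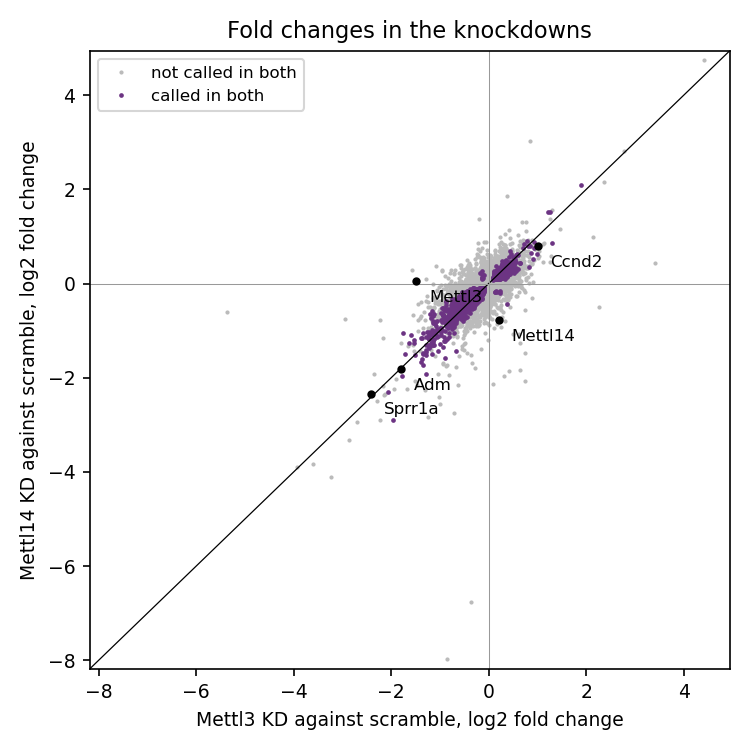
Log2 fold change of each of 14133 genes in Mettl3 KD (horizontal) and Mettl14 KD (vertical) against the same scramble libraries; purple points passed edgeR's test in both, and the black line marks equal change. Adm lies at -1.80 and -1.82, while Mettl3 and Mettl14 lie off the line.

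Compared directly, p53 targets as a group were higher in Mettl3 KD than in Mettl14 KD, and some granule and exocytosis genes were lower. Of 18 p53 targets 7 were higher (7 adjusted over the list alone), with a median of 0.16; this list kept its camera call with an estimated correlation, with adjusted p = 3.44e-06 preset and adjusted p = 0.0113 with an estimated correlation. Ccng1 differed by 0.52 ± 0.05 and Phlda3, a repressor of Akt signalling, by 0.68 ± 0.15, at 3.29 ± 0.505 against 2.05 ± 0.150 CPM. Cdkn1a did not pass edgeR's quasi-likelihood test, at 0.06 ± 0.06 (adjusted p = 0.613).

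Of 16 granule genes 4 were lower in Mettl3 KD than in Mettl14 KD and 1 higher (9 and 1 adjusted over the list alone). Vgf differed by -0.43 ± 0.04 and Ptprn by -0.19 ± 0.03. For these genes camera gave adjusted p = 0.00489 with a preset correlation and adjusted p = 0.646 with an estimated correlation. Of 22 exocytosis genes 6 were lower and 1 higher (6 and 1 adjusted over the list alone); the synaptotagmin Syt13, chosen after its value was seen, differed by -0.26 ± 0.03. Of 39 ribosomal protein genes 2 were higher (2 adjusted over the list alone), with a camera adjusted p = 0.00223 preset and adjusted p = 0.780 with an estimated correlation. In sterol synthesis 1 of 24 was higher and 3 lower (2 and 7 adjusted over the list alone), in glycolysis 2 of 20 higher and 1 lower (2 and 1 adjusted over the list alone), and in oxidative phosphorylation 1 of 35 lower (1 adjusted over the list alone). In glycolysis 1 was higher and 2 lower without scramble replicate 2. Leaving out each knockdown library in turn gave 0 to 2 higher and 0 to 1 lower for glycolysis, and 0 to 1 higher and 1 to 3 lower for sterol synthesis. Without scramble replicate 1, 5 sterol genes were lower. The 1 higher exocytosis gene was not called without Mettl3 KD replicate 1 or Mettl14 KD replicate 1, and 1 ribosomal protein gene was higher without Mettl3 KD replicate 1 or 4 or Mettl14 KD replicate 1 or 2. Camera called 3 of 25 lists with a preset correlation and 1 with an estimated one; it called 5 without scramble replicate 2, adding sterol synthesis with 9 members lower and the mesenchymal, endothelial and immune markers with 2 higher, and 5 without Mettl3 KD replicate 1, adding the writer complex and exocytosis. With all libraries and a preset correlation, the writer complex and exocytosis had adjusted p = 0.0806 each and the mesenchymal, endothelial and immune markers adjusted p = 0.107; with an estimated correlation, adjusted p = 0.646 each and adjusted p = 0.780. It also called sterol synthesis without Mettl14 KD replicate 2. With all libraries that list had adjusted p = 0.0806 preset and adjusted p = 0.780 with an estimated correlation. The median, the mean and the test's direction differed in sign, with small values, for erasers and readers, alpha cell transcription factors, surface markers, and delta, PP and epsilon markers. Without scramble replicate 2, 9 granule genes and 5 oxidative phosphorylation genes were lower and 10 ribosomal protein genes higher. Gcg was lower in Mettl3 KD, at 32823 ± 772 against 37289 ± 1003 CPM, without passing edgeR's quasi-likelihood test, at -0.18 ± 0.06 (adjusted p = 0.0991); without scramble replicate 2, which enters the estimate of spread, it passed at -0.18 ± 0.02.

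Over all genes, edgeR's quasi-likelihood test called 517 higher and 628 lower in Mettl3 KD than in Mettl14 KD, and 17 and 28 of these passed 1.5-fold. The groups did not overlap for 17.6% of genes, against 2.86% by chance. Apart from the targets, the genes named by size were Akr1b7 (1.87-fold), Grap2 (1.76-fold), Fbp2 (1.61-fold), Vwa5b1 (1.61-fold) and Phlda3 (log2 0.68), higher in Mettl3 KD, and Rsc1a1 (1.76-fold), Elmo1 (1.65-fold), Fxyd6 (1.63-fold), AC122442.1 (1.59-fold) and Rabggta (1.58-fold), lower in Mettl3 KD. Rsc1a1 overlaps Ddi2 and its counts are uncertain; its call ended without Mettl3 KD replicate 1 or 4 or Mettl14 KD replicate 1 or 4, at -0.72 to -0.78. Of the genes called against scramble in Mettl3 KD alone, 576 of 2153 passed this direct test, as did 153 of the 689 called in Mettl14 KD alone. The count depended on scramble replicate 2, which enters neither group but shares the estimate of spread: without it 2125 genes were called, and without Mettl3 KD replicate 1 or 4, or Mettl14 KD replicate 1, 3 or 4, between 713 and 762.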

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

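Tests chosen only after the result was seen were those of single scramble libraries, of a culture difference, of shallow sequencing and of a swap; the other splits of the libraries, matched random lists and the lung and blood transcripts not seen before were planned before their results were seen.

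In 12 of 184 groups of 4 libraries, 1 library lay far from the other 3 by Dixon's test over 92 measures. Chance flags about 1 in 20 groups, here 9.2, and scramble, with 3 libraries, was not tested. The total of Mettl14 KD replicate 2 was 20.9 M counts, against 22.3 M in the other Mettl14 KD libraries. In that library E2f1 was at 78.3 CPM (others 86.0 to 87.2) and Gpi1 at 757 CPM (others 847 to 863). In Mettl3 KD, Mgarp was at 3.62 CPM in replicate 3 (others 2.41 to 2.49), Vgf at 179 CPM in replicate 1 (others 160 to 162), Krt7 at 4.45 CPM in replicate 4 (others 3.17 to 3.30), Rbm15 at 48.8 CPM in replicate 3 (others 44.3 to 45.0) and Gpi1 at 872 CPM in replicate 2 (others 917 to 923). In Mettl14 KD, Ttyh1 was at 193 CPM in replicate 3 (others 208 to 210), Foxo3 at 41.1 CPM in replicate 3 (others 38.0 to 38.3), H2-K1 at 37.2 CPM in replicate 1 (others 33.5 to 33.9) and Grap2 at 12.7 CPM in replicate 4 (others 10.5 to 10.9).

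For each count of called genes, the other splits of the libraries argue against a chance division of them. With 35 splits, no share below 1 in 35 could be reached. Those splits mix libraries of both groups, so they cannot tell the knockdown from another difference between the groups, such as culture. Of 35 splits of the 7 libraries of Mettl3 KD and scramble, 1 called as many genes as the real one, the real one itself, with 4420 genes against at most 115 in the others. For Mettl14 KD and scramble it was 1 of 35, with 2956 genes against at most 90. For the 8 libraries of both knockdowns it was 1 of 35, with 1145 genes against at most 1.

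Most sterol synthesis and glycolysis genes fell in each knockdown, 22 of 24 and 18 of 20. Whichever scramble library was left out, at least 40 of the 44 members were lower in each knockdown, which argues against 1 scramble library as the cause, and their median lay at percentile 0 of 10000 random lists matched on length and GC content, which argues against a trend with those. A culture difference of the scramble wells, such as density or oxygen, stays open: it would lower the members alike in both knockdowns. The medians of all 44 members, -0.49 and -0.50, differed by 0.0127, but this pools the lists. In Mettl3 KD and Mettl14 KD the medians were -0.46 and -0.39 for sterol synthesis, and -0.60 and -0.62 for glycolysis. Compared directly, 3 of 24 sterol genes were lower in Mettl3 KD and 1 higher. Counts were 7 and 2 adjusted over the list alone, and 9 and 2 without scramble replicate 2. A shared effect of reducing either subunit would also lower the members alike, and with 1 set of scramble libraries the design gives no test between these explanations.

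Scramble replicate 2 held lung and blood transcripts. Of 17 lung, airway and blood transcripts listed before their values were seen, 16 were highest in that library, where 1.55 would be by chance; Hbb-bt and Lyz1 among them are near copies of Hbb-bs and Lyz2, which had been seen. The 17 summed to 58.8 CPM against at most 5.85 elsewhere; 2 of them, Napsa and Foxj1, were also present in the other libraries, with medians of 1.03 and 1.46 CPM, and Lyz2, among the transcripts seen first, is also in the list of immune markers. Reads from another tissue would give this pattern. The most abundant of the 24 transcripts in that library were Sftpc at 36.1, Scgb1a1 at 34.2, Lyz2 at 19.8 and Sftpb at 11.2 CPM. All 24 held 0.0175% of its counts. That share covers the listed transcripts alone, and the share of all reads from such a tissue was not measured. Shallow sequencing is argued against by the other shallow library, Mettl14 KD replicate 2, at 0.789 times the median of the deeper libraries, and a swap with a knockdown library by Mettl3 and Mettl14, both at least 1.51 times the highest value of their knockdown libraries. No biological explanation was tested.

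Of 35 oxidative phosphorylation genes 20 rose in Mettl3 KD and 21 in Mettl14 KD, and of 39 ribosomal protein genes 26 and 10, so that most of the latter did not pass in Mettl14 KD; scramble replicate 2 had fewer counts on short transcripts. Matched random lists argue against a length trend as the whole cause. With all libraries, the median of both lists together lay at percentile 100 of them in each knockdown. So do the medians after a length trend was removed, 0.14 and 0.18 for oxidative phosphorylation and 0.14 and 0.10 for ribosomal proteins. Scramble replicate 2 alone is argued against as well, since 93.5% of the members called higher stayed so without it in each knockdown. These were 43 of 46 and 29 of 31, though the medians were smaller. Without it, oxidative phosphorylation lay at percentiles 98.8 and 100 of matched lists in Mettl3 KD and Mettl14 KD, and ribosomal proteins at 99.7 and 97.9. In Mettl14 KD the ribosomal median, 0.0767, was close to the matched lists' upper bound of 0.0743. Length and that library together are therefore less clearly argued against there. A biological change remains a hypothesis, and a culture difference of the scramble wells was not tested for these genes.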

How the results depend on the processing

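Leaving out both shallow libraries, and correcting for transcript length, were tests chosen only after the data were seen. Over 22 alternatives, 131 values of named genes gave 2882 alternative values, of which 2765 kept direction and side of the threshold, 108 no longer passed, 7 newly passed and 2 reversed, both for Gcg in Mettl3 KD. Its log2 fold change without 1 library ran from -0.14 to 0.0266, at 0.0118 without scramble replicate 1, 0.0266 without scramble replicate 3 and -0.14, past the threshold, without scramble replicate 2. A test against a fold of 1.2 called 453, 238 and 19 genes for Mettl3 KD, Mettl14 KD and their difference, since it asks for larger changes. The difference between knockdowns had 1145 calls, and 2038 with quality weights in limma-voom, 2187 with only the 2 groups fitted and 1872 without both shallow libraries. The last 2 settings remove scramble replicate 2. Without that library alone there were 2125 calls, against 1199 without scramble replicate 1 and 1140 without scramble replicate 3. Why quality weights raised the count was not tested. Leaving out 1 library gave 713 to 2125 for that count, 3705 to 4343 for Mettl3 KD, 2276 to 3091 for Mettl14 KD and 1811 to 2369 for calls shared in direction. Pearson's r, 0.736, was 0.675 with DESeq2 and 0.614 without a low-count filter, where more genes with few counts enter, 0.793 with at least 1 CPM in 3 samples, and 0.712 to 0.802 without 1 library. Camera called 9, 9 and 3 lists, and 0, 0 and 1 with an estimated correlation, and fry, which tests whether a list moves one way, 12, 10 and 4; without 1 library camera called 6 to 11, 8 to 10 and 3 to 5, and without both shallow libraries 5 for the difference. Replicate numbers gave no sign of pairing the libraries. Between same-numbered libraries of different groups, deviations of log2 CPM from the group mean correlated at -0.118 to 0.0674 over 10 pairs. Pairs with different numbers were not compared. With the replicate number as a block, 3784, 2335 and 839 genes were called and 1787 shared. What depth limits was not tested apart from other noise: at the real depths, 53.7% of simulated 1.2-fold changes were recovered for Mettl3 KD against scramble. That simulation changed far fewer genes than were called in the data, so the share may be an underestimate.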

Other observations

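The lists of hypoxia-inducible and fatty acid genes were written after some of their members had been seen to fall; the tests below on members not seen before, and the test of motifs, were planned before their results were seen.

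Hypoxia-inducible genes fell in both knockdowns beyond glycolysis. Ndrg1, a stress-response gene, changed by -1.12 ± 0.05 on the log2 scale in Mettl3 KD and -1.17 ± 0.05 in Mettl14 KD, Bnip3, a mitophagy receptor, by -1.15 ± 0.11 and -1.30 ± 0.11, and Vegfa, a vascular growth factor, by -0.69 ± 0.03 and -0.59 ± 0.03. Of 22 further hypoxia-inducible genes not looked at before, 20 were lower in both knockdowns, 90.9%, with medians of -0.56 and -0.58. Egln3, an oxygen-sensing prolyl hydroxylase, was at -1.22 ± 0.18 and -1.35 ± 0.18, and Ak4, a mitochondrial adenylate kinase, at -1.04 ± 0.13 and -1.43 ± 0.13. Pfkfb4 and Pgm2 did not pass edgeR's test in either. A lower oxygen response in the knockdown cultures is a candidate explanation, and whether it follows from the knockdowns or from a difference of the scramble wells stays open, as for glycolysis.

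Fatty acid genes also fell. The desaturases Scd1 and Scd2 were at -1.22 ± 0.04 and -1.16 ± 0.04 in Mettl3 KD and at -1.09 ± 0.04 and -1.06 ± 0.04 in Mettl14 KD. Of 15 further fatty acid genes not looked at before, 10 were lower in both knockdowns, 66.7%, with medians of -0.24 and -0.19. Srebf1, a transcription factor of lipid synthesis, was at -0.75 ± 0.05 and -0.71 ± 0.05, and Acss2, acetyl-CoA synthetase, at -0.60 ± 0.05 and -0.62 ± 0.05. Me1, Mid1ip1, Pnpla3 and Hsd17b12 passed in neither knockdown and Elovl5 in Mettl14 KD alone. This may reflect a lower SREBP programme, with the same open question about the scramble wells.

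Fold changes against scramble showed no positive relation to motifs for m6A beyond that of other splits. Over 11361 genes, the difference of mean log2 CPM was correlated with the number of motifs far from exon junctions. This partial Spearman correlation was adjusted for length, GC content, mean log2 CPM and motifs near junctions. It was 0.00213 in Mettl3 KD, where 34 other splits of the libraries gave -0.0166 to 0.0253. In Mettl14 KD it was -0.0182, where they gave -0.0300 to 0.0307. Between Mettl3 KD and Mettl14 KD it was 0.0249, where 2 of 68 other splits were as high, up to 0.0293. With edgeR's log2 fold changes the partial correlations were 0.00347, -0.0175 and 0.0248 in that order. Unadjusted correlations with these fold changes were negative, at -0.141, -0.0971 and -0.108. Motifs are a stand-in for m6A, which was not measured, and genes are not independent replicates. Whether this adjusted correlation would find a real effect was not tested, so values near 0 do not exclude one.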
